A study of Mus musculus with 20 samples.

How the data were processed

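Expression was measured by RNA sequencing of hypothalamus slices from wild-type C57BL/6 mice in 20 libraries. Per the labels' protocols, total RNA was extracted with a column kit and sequenced as paired-end reads of 150 bp on a DNBseq instrument, which reads amplified DNA nanoballs. The labels place 7 libraries in a control group fed ad libitum, 7 in a group given a risperidone diet ad libitum and 6 in a group given the risperidone diet by pair-feeding, in which the amount of food is limited to that eaten by a reference group. The risperidone diet lasted 4 weeks. The labels state that body weights did not differ from mice on the control diet, and their wording does not settle whether this covers 1 or both feeding conditions. Each library was taken as 1 sample of its group. The labels do not say outright that each library came from a separate mouse, so the p-values measure the spread between these samples, which may be in part technical.

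The authors deposited 1 table of raw counts of reads per gene, as whole numbers with no normalization, with 1 column per library. STAR, featureCounts and DESeq2 are the tools named, per the submitters' processing notes, with the builds GRCm38 and mm10. Their versions, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Because the strand setting is not given, counts of a gene that overlaps another gene on the opposite strand are uncertain. The table held 55471 genes, of which 55144 were matched by identifier to a symbol and a position in the GENCODE annotation of GRCm38 and 327 were not. The unmatched genes held 0.0448% of the counts, and 13801 genes had no count in any library. All value columns belonged to the 20 libraries.

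Total counts ranged from 17316043 to 18606543 in 19 libraries, and risperidone ad libitum library 3 held 9748005 counts. In that library 26.8% of the counts fell in 6 genes annotated as or resembling ribosomal RNA, against 1.49% to 4.62% in the others. Counts of pairs of libraries in the same group were compared with a chi-square test over genes with a sum of at least 20 counts. The lowest chi-square per degree of freedom among the 57 pairs was 2.65, so that no pair differed by as little as sampling noise and every library was counted once.

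Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Library sizes were scaled with TMM, genes were kept with filterByExpr at its minimum count of 10, and 1 model with a coefficient per group was fitted to the 20 libraries. This left 17893 genes, with a common biological coefficient of variation of 11.26%. All tests were two-sided. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 4 comparisons were ad libitum risperidone against control, pair-fed risperidone against control, pair-fed against ad libitum risperidone, and the mean of both risperidone groups against control. The comparison of the risperidone groups is also the difference between their changes against control. Fold changes are given on the log2 scale with their standard error (SE) or 95% interval, and levels as TMM-scaled counts (CPM, from the cpm function of edgeR) with the standard deviation (SD) between libraries. Log values per library used a prior count of 2.

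Before the data were examined, 38 gene lists with 658 memberships were fixed, of which 631 were measured. They comprised 17 lists of pathways and gene groups and 21 lists of markers of cell types and brain regions that a hypothalamus slice could hold, and 31 genes stood in 2 or more lists. Each list was tested against the other genes with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 38 lists. The same test with an estimated correlation, and fry, which tests whether the genes of a list move on balance in 1 direction, were the alternatives. Counts of changed list members are given over all genes tested and adjusted over the list alone.

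The genes named were chosen by a rule fixed before the data were examined. Mc4r, Agrp, Pomc, Npy, Drd2, Htr2a and Htr2c were always named. In each comparison up to 10 genes that rose and 10 that fell with the smallest p were added (5 for the mean of both groups), with a mean of at least 1 CPM and leaving out predicted genes, pseudogenes and genes with no symbol. If fewer than 5 genes passed in a direction, the 5 with the smallest p were named. Up to 4 members per list with the smallest p were added as examples. A gene named outside this rule is said to be chosen after its values were seen.

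The alternatives planned before the data were examined were 2 other scalings (RLE and upper quartile), no low-count filter or a minimum mean of 1 CPM, DESeq2 1.42.0, limma-voom with quality weights, robust dispersion estimates, a fit to the groups compared alone (for the mean of both risperidone groups, a fit with these as 1 group), replicate numbers as a block, 2 surrogate variables (sva 3.50.0), the first principal component of the marker lists as a covariate, an adjusted p under 0.1, and each library left out in turn. A fit without risperidone ad libitum libraries 1 and 3, and one on protein-coding genes alone, were chosen after seeing the data. Overlap between the comparisons that share the control libraries was compared with 100 simulated pairs of unchanged groups and with the 70 ways of splitting the controls between the comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

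The tests were tested on simulated data drawn from the means and library sizes of the real libraries. For ad libitum risperidone against control, with 17797 genes tested, the test called 44.8% of 67 genes changed 1.25-fold, 53.7% of 67 changed 1.5-fold and 95.5% of 66 changed 2-fold, and 11 of its 148 calls were false. For pair-fed risperidone against control, with 17783 genes tested, the shares were 47.8%, 68.7% and 89.4%, with 5 false among 149 calls. For pair-fed against ad libitum risperidone, with 17788 genes tested, they were 35.8%, 73.1% and 86.4%, with 5 false among 146 calls. For the mean of both groups against control, with 17790 genes tested, they were 64.2%, 82.1% and 95.5%, with 9 false among 181 calls. In each of the 4 simulations a list of 20 genes shifted 1.25-fold was found and 0 of the other lists were called, by camera with either correlation and by fry. The simulated genes were drawn independently of each other. The list tests were therefore not tried on lists whose genes are correlated, as those of the real lists are.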

Results

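Gene expression was compared in hypothalamus slices of C57BL/6 mice in 3 groups that differed in diet or feeding. Risperidone is an atypical antipsychotic that blocks dopamine D2 and serotonin 2A receptors, among others, and weight gain is a known side effect of it. The title of the series names central melanocortin 4 receptors, which restrain food intake, as its question. There were 7 libraries from mice on control diet ad libitum, 7 from mice on risperidone diet ad libitum and 6 from pair-fed mice on risperidone diet. Counts of reads per gene totalled between 17352462 and 18493768 in the control libraries and between 17318502 and 18314306 in the pair-fed libraries. In the ad libitum risperidone group, library 3 held 9748005 counts and the other libraries 17316043 to 18606543. In that library 26.8% of the counts fell in the genes annotated as or resembling ribosomal RNA, against 4.62% or less elsewhere. Markers of cortex, hippocampus and amygdala had a mean log2 CPM of 6.06 in ad libitum risperidone library 1 and of 3.07 to 3.88 in the other libraries of its group. The first 2 principal components of the genes tested held 20% and 17% of the variance.

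**Figure D1:**
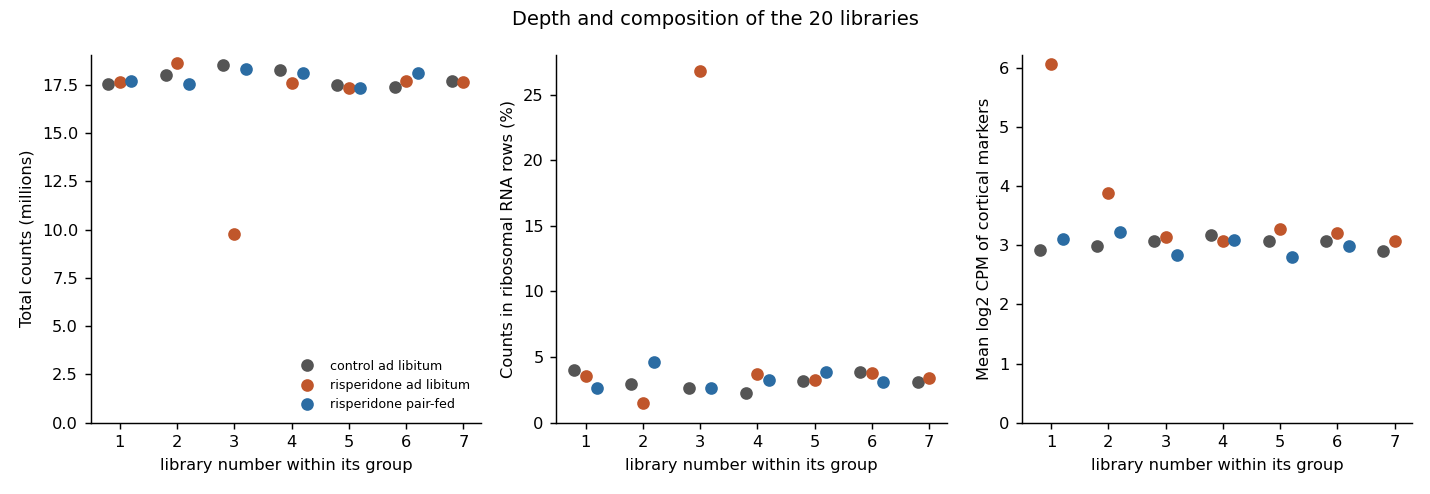
Points show the total counts, the percentage of counts in genes annotated as or resembling ribosomal RNA and the mean log2 CPM of the markers of cortex, hippocampus and amygdala in each of the 20 libraries, by library number within its group. Risperidone ad libitum library 3 lies apart at 9748005 counts and 26.8%, and risperidone ad libitum library 1 at a marker level of 6.06.

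Mc4r, the gene of the melanocortin 4 receptor, was measured at 5.82 ± 0.919 CPM (SD, n = 7) in control, 4.07 ± 0.687 CPM (SD, n = 7) in ad libitum risperidone and 4.17 ± 0.213 CPM (SD, n = 6) in pair-fed risperidone hypothalamus. It is annotated on chromosome 18 from 66857704 to 66860506 in GRCm38 (ENSMUSG00000047259), with no overlapping gene. Its log2 fold change was −0.49 (95% interval −0.71 to −0.27) in ad libitum risperidone against control, with each of the 7 libraries below every control library, but an adjusted p of 0.0736 (0.0149 to 0.196 over 33 other settings, under 0.05 in 2) kept it outside the threshold. In pair-fed risperidone it fell by 0.48 on the log2 scale (SE 0.108, adjusted p = 0.0419, edgeR), again with all 6 libraries below every control library. Over the mean of both risperidone groups it fell by 0.49 (SE 0.0901, adjusted p = 0.0113). Between the risperidone groups its difference was 0.01 (95% interval −0.23 to 0.24, adjusted p = 0.99). These values rest on low counts, 89 to 141 reads per control library, 19 to 93 in the ad libitum and 67 to 82 in the pair-fed libraries. The call in pair-fed risperidone was lost in 17 of 33 other settings, with adjusted p values between 0.00395 and 0.137, and that over the mean of both groups was kept in all 33.

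**Figure D2:**
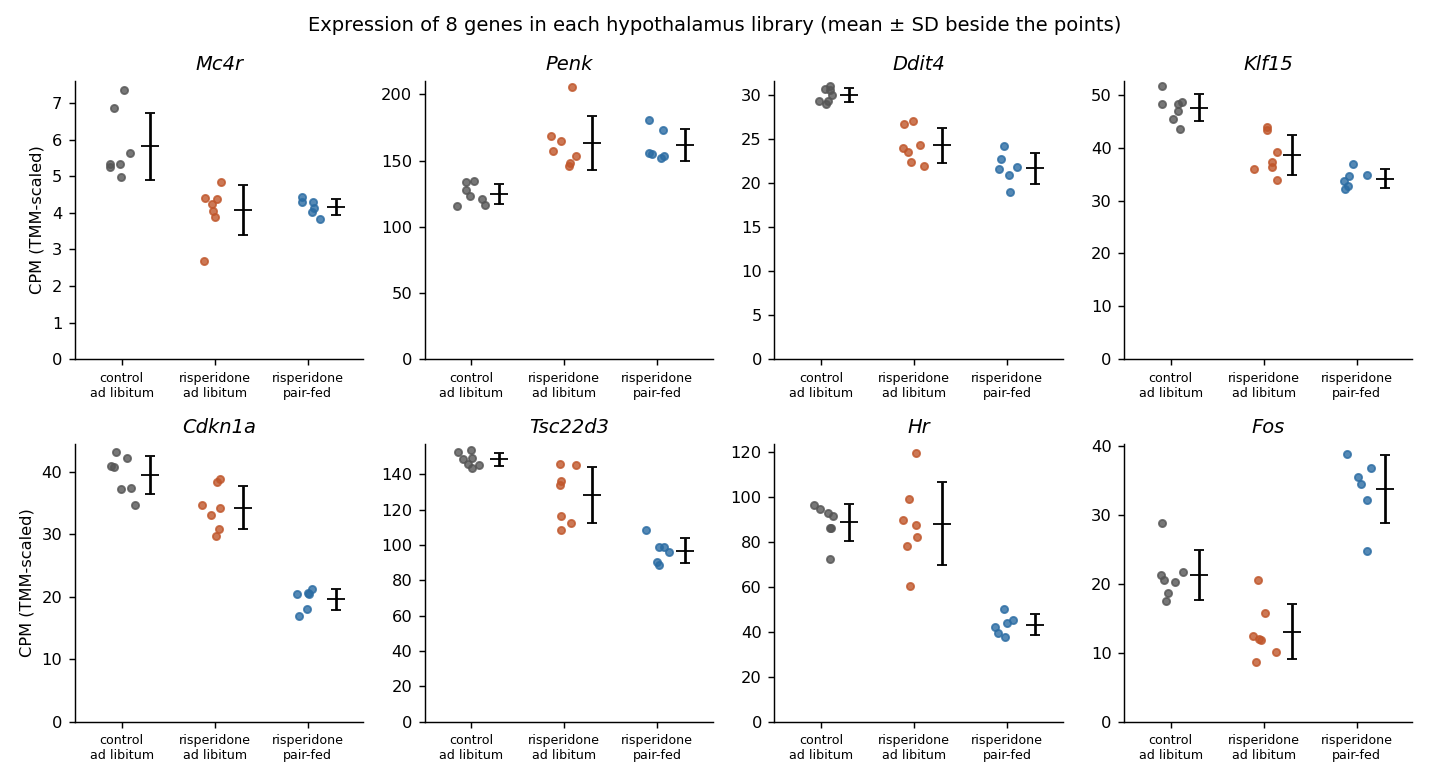
Points show the expression of 8 genes in CPM in each library of control (n = 7), ad libitum risperidone (n = 7) and pair-fed risperidone (n = 6), with the mean and SD beside them. Mc4r lies lower in both risperidone groups (means 4.07 and 4.17 CPM against 5.82), while Cdkn1a, Tsc22d3, Hr and Fos differ between the risperidone groups.

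The other genes fixed in advance passed the test in 0 of the 4 comparisons with edgeR. Pomc, the precursor of the anorexigenic melanocortin peptides, was at 52.7 ± 7.14 CPM (SD, n = 7) in control and had a log2 fold change of −0.57 (95% interval −0.93 to −0.20, adjusted p = 0.201) in ad libitum and of −0.33 (−0.70 to 0.05, adjusted p = 0.823) in pair-fed risperidone. Npy, which codes for the orexigenic neuropeptide Y, had values of 0.25 (−0.06 to 0.56) and 0.27 (−0.05 to 0.59). Agrp, which codes for the antagonist of the melanocortin receptors, had values of −0.13 (−0.48 to 0.21) and 0.24 (−0.10 to 0.58), and its annotated span overlaps Ripor1 and Ctcf on the opposite strand, so that its counts are uncertain. The drug's receptor targets had intervals that included 0. Drd2 had log2 fold changes of −0.05 (−0.29 to 0.20) in ad libitum and −0.06 (−0.31 to 0.19) in pair-fed risperidone, Htr2a of 0.07 (−0.15 to 0.29) and −0.08 (−0.31 to 0.14), and Htr2c of 0.10 (−0.13 to 0.32) and 0.13 (−0.10 to 0.36).

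The comparison of ad libitum risperidone with control asked what the diet changed when food was free. Penk, which codes for the enkephalin precursor, rose from 125 ± 7.61 to 163 ± 20.4 CPM (SD, n = 7 each), a log2 fold change of 0.39 (SE 0.0655, adjusted p = 0.0343) with 7 of 7 libraries above the control mean. A2m, a protease inhibitor, rose by 0.83 (SE 0.143, adjusted p = 0.0343) and Spry1, an inhibitor of receptor tyrosine kinase signalling, by 0.40 (SE 0.0737, adjusted p = 0.0347). Among the genes that fell were Ddit4, an inhibitor of mTORC1 that glucocorticoids induce, at −0.30 (SE 0.0529), Klf15, a transcription factor that glucocorticoids induce, at −0.31 (SE 0.0545), and F3, which codes for tissue factor, at −0.29 (SE 0.0486), each with an adjusted p of 0.0343. Rrad, which codes for a small GTPase that restrains calcium channels, fell by 0.66. Sytl4, which acts in the docking of secretory granules, fell by 0.64 and Arl4d, which codes for another small GTPase, by 0.59. Gadd45g, a gene of the growth arrest response, fell by 0.46 and Txnip, which codes for the thioredoxin-interacting protein, by 0.44. Rrad overlaps a predicted gene on the opposite strand and its counts are uncertain in that respect.

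In all, 3 genes rose and 8 fell of the 17893 tested in ad libitum risperidone, and 2345 had an unadjusted p under 0.05. Tanc1 (0.48, SE 0.0975) and Ptprd (0.23, SE 0.0482) were next among the higher genes, each with an adjusted p of 0.0736. The adjusted p values of the 11 genes lay between 0.0343 and 0.044, and each call was lost in 9 to 16 of 33 other settings. Adjusted p values there reached 0.084 for Penk and 0.117 for Arl4d. Other tools called more genes on the same libraries, DESeq2 113 and limma-voom 51. In simulated data for this comparison DESeq2 made 23 false calls beside 134 true ones, edgeR 11 beside 129 and limma-voom 9 beside 127. These were drawn with independent genes and no library that stands apart in makeup, so they do not explain the counts on the real libraries. With edgeR the count was 0 without control library 1, 2, 3, 4 or 5 or without ad libitum library 2 or 7, 1 without control library 6, 5 without ad libitum library 6, and 27 without ad libitum library 4. It was 35 without ad libitum library 1 and 48 without ad libitum libraries 1 and 3. Between 1824 and 2303 genes had an unadjusted p under 0.05 where the count was 0.

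Of the 38 gene lists, 14 shifted in ad libitum risperidone with camera, 2 towards higher and 12 towards lower values. Of these, 0 shifted with an estimated correlation, where 6 had an unadjusted p under 0.05, and 4 with fry. Those 4 were the glucocorticoid-responsive, feeding circuit, other neuropeptide and ependyma lists (adjusted p = 0.0298 each with fry). The glucocorticoid-responsive genes shifted lower, with a median of −0.21 and 1 of 20 fallen over all genes (Ddit4), or 8 fallen and 2 risen adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). Its mean was −0.04, nearer to 0 than the median because of Lcn2 at 2.25 (SE 0.754) and Gpd1 at 0.48 (SE 0.123). Errfi1 (−0.27), Nfkbia (−0.27) and Pdk4 (−0.44) were its next members by p, outside the threshold over all genes. The melanocortin and leptin feeding circuit shifted lower with a median of −0.10, 0 of 18 members fallen over all genes and 4 adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). After Mc4r its members with the smallest p were Cartpt (−0.31), Pomc (−0.57) and Mc3r (−0.31). Other hypothalamic neuropeptides shifted lower with a median of −0.12, with Gal at −0.37, Ghrh at −0.46 and Pdyn at −0.36 not past the test and Penk risen, 1 of 26 over all genes, against 3 risen and 6 fallen adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). The immediate early genes had a median of −0.04, a mean of 0.04 and a camera test towards lower values (adjusted p = 0.0388, and 0.851 with an estimated correlation), with Fos at −0.68 (SE 0.146, adjusted p = 0.0736); without ad libitum libraries 1 and 3 the median was −0.26.

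Several marker lists moved with this group too. Markers of cortex, hippocampus and amygdala shifted higher with a median of 0.80, led by Slc17a7, the vesicular glutamate transporter of cortical neurons, at 3.94 (SE 0.923, adjusted p = 0.105), and 8 of 11 rose adjusted over the list alone, 0 over all genes (adjusted p = 0.6 with an estimated correlation). Without ad libitum libraries 1 and 3 that median was 0.15. Ependyma markers, genes of the ciliated cells that line the ventricles, shifted lower with a median of −0.30 and lower values in 10 of 10 members, 7 of them fallen adjusted over the list alone and 0 over all genes (adjusted p = 0.112 with an estimated correlation). Markers of the paraventricular and supraoptic nuclei, where Mc4r is expressed, shifted lower with a median of −0.33 (adjusted p = 0.216 with an estimated correlation), as did those of pericytes and fibroblasts with −0.38 (0.558) of the arcuate nucleus with −0.13 (0.312) and of the lateral hypothalamus with −0.08 (0.275). Thalamus markers shifted higher with a median of 0.17 and 10 of 12 members higher (0.645). Interferon-response genes had a median of −0.28 (adjusted p = 0.335 with an estimated correlation), with Irf7 at −0.64 and Ifit1 at −0.72. The cytoplasmic ribosomal protein and heat shock lists shifted lower with a median of −0.07 each (adjusted p = 0.736 and 0.6 with an estimated correlation), and without ad libitum libraries 1 and 3 their tests gave adjusted p values of 0.664 and 0.271.

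The comparison of pair-fed risperidone with control changed diet and feeding together, since the controls were fed ad libitum and no pair-fed control group was among the libraries. Of 20 genes that respond to glucocorticoids 13 fell. Cdkn1a, which codes for the cell cycle inhibitor p21, fell from 39.5 ± 3.09 CPM (SD, n = 7) to 19.6 ± 1.69 CPM (SD, n = 6), a log2 fold change of −1.01 (SE 0.0707, adjusted p = 2.22e-08). Tsc22d3, which codes for the glucocorticoid-induced leucine zipper, fell from 148 ± 3.88 to 96.9 ± 7.06 CPM, −0.62 (SE 0.0654, adjusted p = 1.54e-05). Nfkbia, which codes for an inhibitor of NF-κB, fell by 0.53 (SE 0.0601) and Ddit4 by 0.47 (SE 0.0551). Klf15, which is not among these 20 genes, fell by 0.48 (SE 0.0568). Penk rose by 0.37 (SE 0.0679, adjusted p = 0.00571) in 6 of 6 libraries, as it did in the ad libitum group.

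The list of glucocorticoid-responsive genes had 13 of its 20 members fallen over all genes and 14 adjusted over the list alone, 0 risen and a median of −0.57 (adjusted p = 5.74e-07 with an estimated correlation). In this list Fkbp5, Plin4 and Zbtb16, chosen after their values were seen, fell by 0.91, 1.68 and 1.13. Members that did not pass included Per1 at 0.00, Mt1 at −0.10 and the glucocorticoid receptor gene Nr3c1 at 0.05. Endoplasmic reticulum stress genes shifted lower with a median of −0.13, with Pdia4, a chaperone, fallen by 0.28 and 8 of 22 members fallen adjusted over the list alone (adjusted p = 0.393 with an estimated correlation). The melanocortin and leptin feeding circuit shifted lower with a median of −0.09, with Mc4r fallen over all genes and 4 of 18 members adjusted over the list alone. Its adjusted p was 0.0724 with an estimated correlation and 0.0393 with fry. Npy1r, a receptor for neuropeptide Y, stood at −0.30 and Mc3r at −0.37, neither past the test. Immediate early genes, which neuronal activity induces, shifted higher with a median of 0.28, with 1 of 21 risen over all genes, and 3 risen and 1 fallen adjusted over the list alone (adjusted p = 0.618 with an estimated correlation). Fos, the member that rose over all genes, went from 21.2 ± 3.63 to 33.7 ± 4.96 CPM, a log2 fold change of 0.67 (SE 0.143, adjusted p = 0.029).

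**Figure D3:**
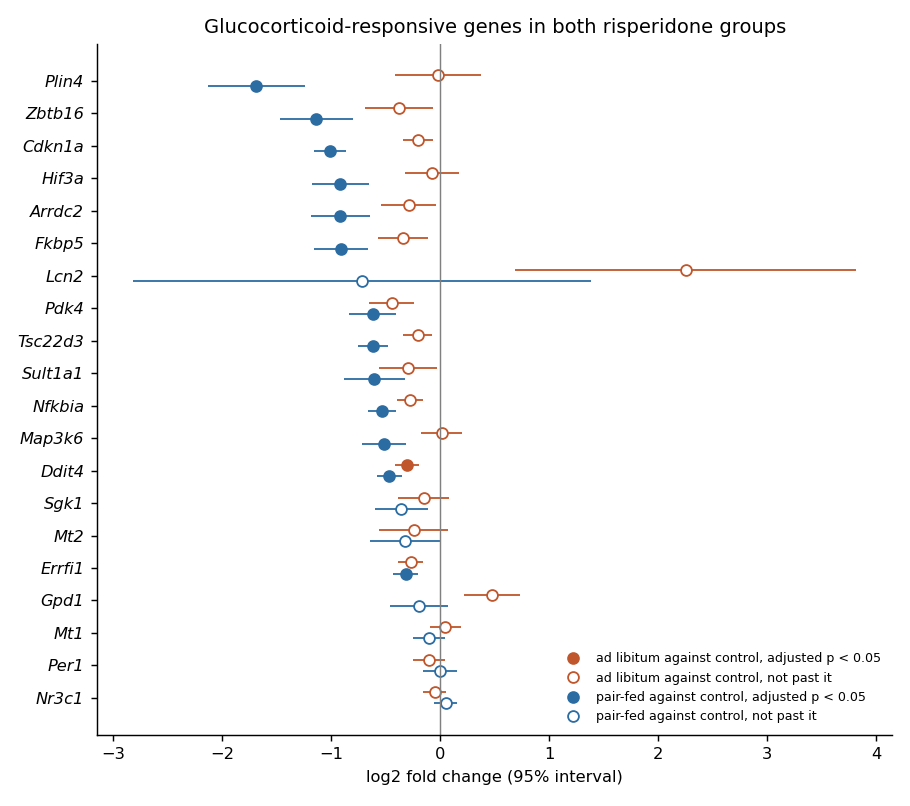
Points and bars show the log2 fold change and its 95% interval for the 20 glucocorticoid-responsive genes in ad libitum and in pair-fed risperidone against control, filled where the adjusted p was under 0.05. In pair-fed risperidone 13 genes fell, with a list median of −0.57, and in ad libitum risperidone 1 fell, with a list median of −0.21.

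Genes outside that list fell in pair-fed risperidone too. Mfsd2a, the transporter that carries docosahexaenoic acid across the blood-brain barrier, fell from 51.4 ± 3.33 to 29.5 ± 2.09 CPM, −0.80 (SE 0.0634, adjusted p = 1.31e-07), and Slc2a1, the glucose transporter of that barrier, by 0.44 (SE 0.0521), with predicted genes on its opposite strand. Hr, which codes for a nuclear receptor corepressor, fell by 1.04 (SE 0.109), Mertk, a receptor for the uptake of dying cells, by 0.73 (SE 0.0873) and Smim3 by 0.59 (SE 0.0688). The genes that rose included the transcription factor Sox21 by 0.52 (SE 0.0793, adjusted p = 0.00072), Wnt7a, a Wnt ligand, by 0.45, Sytl2 by 0.46, Plekho2 by 0.37 and Gkn3 from 1.09 to 2.61 CPM (SE 0.26 on the log2 scale). Dbp, a transcription factor of the clock output, rose by 0.32 and Pfn4 by 0.30, and these overlap Sphk2 and Fam228b on the opposite strand, so that their counts are uncertain. Some of these calls were lost in many of the 33 other settings, that of Pfn4 in 22, Wnt7a in 14, Fos in 12, Pdia4 in 11, and Gkn3 and Dbp in 9 each. In all, 9 genes rose and 78 fell of 17893, with 1191 at an unadjusted p under 0.05. The count was 166 without ad libitum library 1, which enters through the shared estimate of the spread, 245 in a fit without the ad libitum risperidone group and 250 without its libraries 1 and 3. Of the 38 lists 14 shifted, 9 towards higher and 5 towards lower values. Of these, the glucocorticoid-responsive list alone held with an estimated correlation. With fry 2 lists shifted, this one and the melanocortin and leptin feeding circuit.

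Between the comparisons with control, 6 genes changed in both risperidone groups with the same sign. Penk rose in both, and Txnip, F3, Klf15, Ddit4 and Arl4d fell in both. Independent lists of these sizes would share 0.00151 risen and 0.0349 fallen genes, and in 100 simulated pairs of unchanged groups against the same controls the means were 0 and 0.01. The simulated groups had means of 0.07 and 0.02 calls, so that they had hardly any calls to share and give no chance level for lists of 11 and 87 genes. With the controls split between the comparisons in 70 ways, 0 genes were shared. With edgeR the ad libitum group then had a mean of 0.0286 calls and the pair-fed group 46.6, so that the split left hardly any ad libitum calls to share. The overlap was 19 genes with DESeq2, 21 with limma-voom and 21 without ad libitum libraries 1 and 3. With edgeR it was 0 without control library 1, 2, 3, 4 or 5 or ad libitum library 2 or 7, where the ad libitum comparison had no calls, 1 without control library 6, 3 without ad libitum library 6, 12 without ad libitum library 4 and 14 without ad libitum library 1. Over all genes the fold changes of both comparisons had a correlation of 0.328 and a covariance of 0.0126, against 0.472 and 0.0115 (range 0.0103 to 0.0124) in the simulated pairs and means of 0.102 and 0.00475 with split controls. These are correlations across genes, which are not independent replicates. The sign was the same in both comparisons for 60.6% of all genes, against 65.7% in the simulated pairs.

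The comparison of pair-fed with ad libitum risperidone asked what the feeding condition changed on the same diet. Of 21 immediate early genes, 3 rose in pair-fed mice, 16 had higher and 5 lower values, and the list's shift was not past the test with an estimated correlation (adjusted p = 0.584) or with fry (0.263). Fos was at 33.7 ± 4.96 CPM (SD, n = 6) against 13.1 ± 3.98 CPM (SD, n = 7) and rose by 1.35 (SE 0.149, adjusted p = 2.32e-05) in 6 of 6 libraries. Fosb rose by 0.91 (SE 0.153) and Fosl2 by 0.75 (SE 0.124), each with an adjusted p of 0.004, as did Rrad by 0.87 (SE 0.115, adjusted p = 0.000369). The list of immediate early genes had a median of 0.17 and 6 members risen adjusted over the list alone, and without ad libitum libraries 1 and 3 the median was 0.40.

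The glucocorticoid-responsive genes were lower in pair-fed than in ad libitum risperidone, with 9 of 20 fallen over all genes, 12 adjusted over the list alone and a median of −0.36 (adjusted p = 0.00122 with an estimated correlation). Cdkn1a fell by 0.81 (SE 0.0713, adjusted p = 1.09e-06), Plin4, which codes for a lipid droplet protein, from 48 ± 20.1 to 14.8 ± 3.71 CPM or by 1.67 (SE 0.214), Hif3a, which codes for a hypoxia-inducible factor subunit, by 0.84 (SE 0.127) and Tsc22d3 by 0.41 (SE 0.0654). Ddit4, which fell against control in both risperidone groups, stood at −0.17 between them (adjusted p = 0.216). Mfsd2a fell by 0.75, Hr by 1.02, Mertk by 0.62 and Fam107a, a gene expressed in astrocytes, by 0.57 (SE 0.0595, adjusted p = 1.42e-05). Glul, which codes for glutamine synthetase, fell by 0.30, the proteoglycan gene Sdc4 by 0.36, the protease gene Htra1 by 0.43 and Tekt4, which codes for a protein of ciliary microtubules, by 0.80. Plin4, Htra1 and Glul overlap Hdgfl2, Fgfr2 and Teddm2 on the opposite strand. Other genes that rose were Nes, which codes for the filament protein nestin, by 0.53, Sox21 by 0.45, Dbp by 0.37, Coq10b by 0.37, Twistnb, a subunit of RNA polymerase I, by 0.31 and the receptor Gpr3 by 0.48. Gpr3 and Coq10b also overlap other annotated genes.

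In all, 20 genes rose and 51 fell between the risperidone groups, with 2422 at an unadjusted p under 0.05. The count was 130 without ad libitum library 1, 142 without ad libitum libraries 1 and 3, 47, 41, 40 and 39 without pair-fed library 1, 4, 5 or 6, and 31 in a fit to these groups alone. Of the 38 lists 16 shifted, 11 towards higher and 5 towards lower values, of which the glucocorticoid-responsive list held with an estimated correlation and was the list that shifted with fry. Ependyma markers had a median of 0.28 with higher values in 10 of 10 members (adjusted p = 0.52 with an estimated correlation), interferon-response genes of 0.29 (0.584), and markers of cortex, hippocampus and amygdala of −0.87 (0.584), which was −0.17 without ad libitum libraries 1 and 3. Markers of pericytes and fibroblasts (0.39, 11 of 12 higher), the paraventricular and supraoptic nuclei (0.20) and the arcuate nucleus (0.08) shifted higher and those of thalamus (−0.22) lower, each with an adjusted p of 0.584 with an estimated correlation, and those of oligodendrocyte precursors (−0.16) lower (0.52). Without ad libitum libraries 1 and 3 the paraventricular and arcuate lists did not shift (adjusted p = 0.084 and 0.147).

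**Figure D4:**
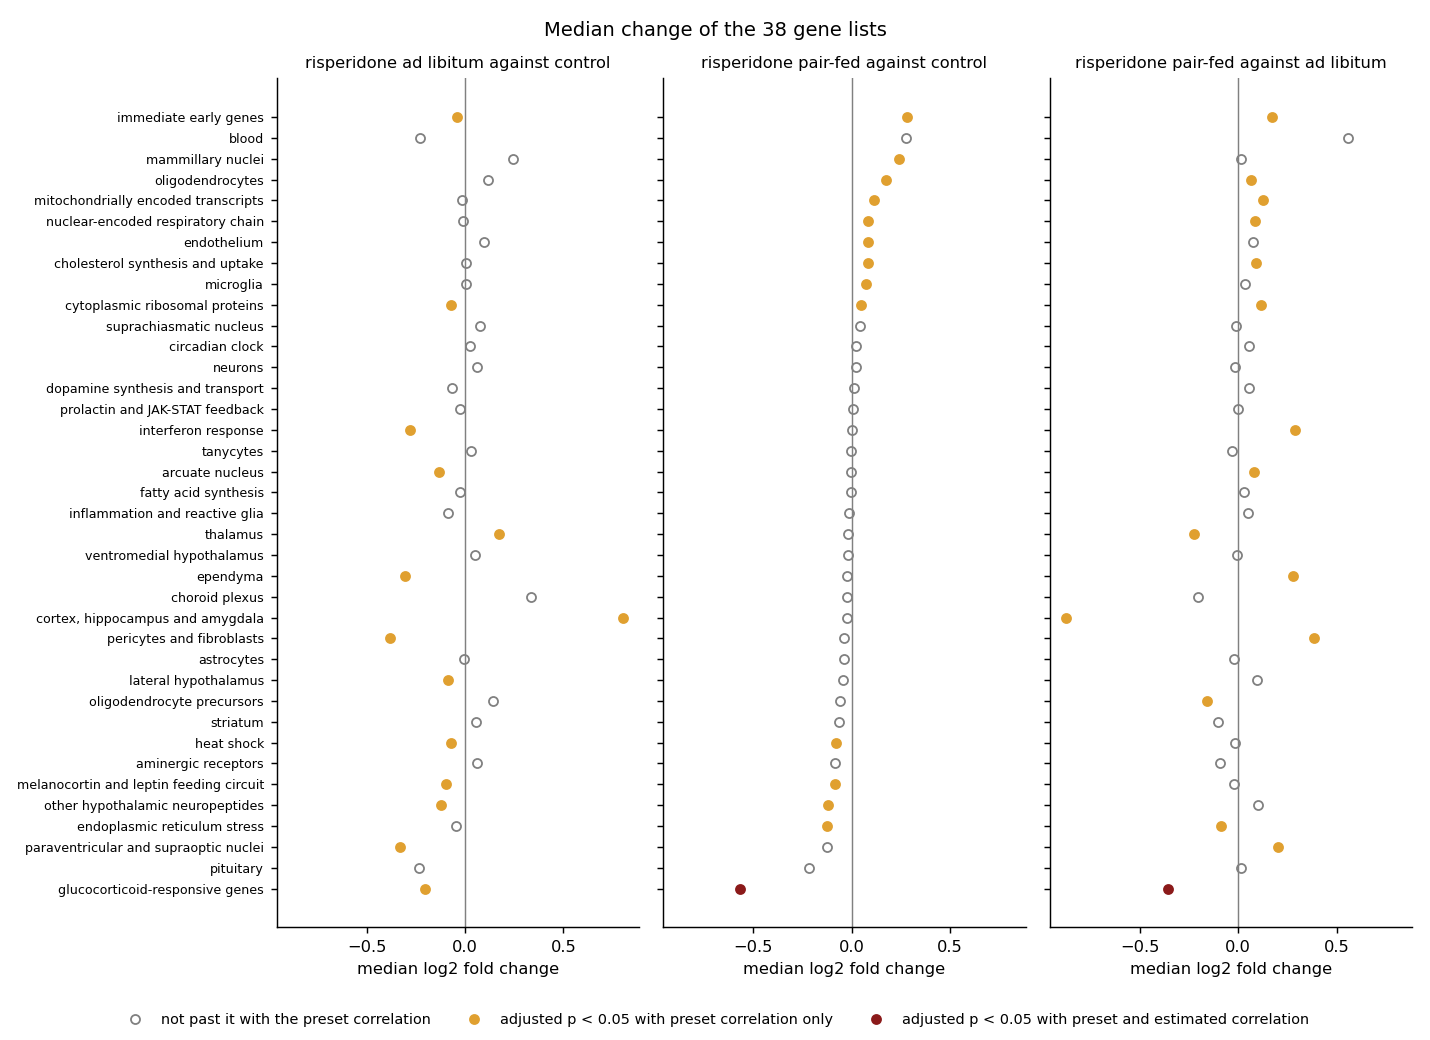
Points show the median log2 fold change of each of the 38 gene lists in 3 comparisons, filled where camera gave an adjusted p under 0.05, with the darker fill where this held with an estimated correlation too. The glucocorticoid-responsive genes lie at −0.21, −0.57 and −0.36, and the latter pair of values held with an estimated correlation.

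The mean of both risperidone groups against control asked how these groups differed on average from the controls fed ad libitum. A change in 1 of the groups alone can pass this test. Penk rose by 0.38 (SE 0.0582, adjusted p = 0.00182) in 13 of 13 libraries, A2m by 0.66 (SE 0.128) and Plekho2 by 0.32 (SE 0.0658), while Fam53b at 0.21 and Map6d1 at 0.29 did not pass (adjusted p = 0.0579 and 0.0588). Cdkn1a fell by 0.61 (SE 0.0573), Klf15 by 0.39, Nfkbia by 0.40 and Mfsd2a by 0.43, and Ddit4 had a log2 fold change of −0.38 (SE 0.0458, adjusted p = 0.000171) in 13 of 13 libraries. For Cdkn1a, Mfsd2a and Tsc22d3 this mean joined groups that differed from each other. The call of Plekho2 was lost in 10 of 33 other settings (adjusted p up to 0.0869) and that of A2m in 5 (up to 0.0629), while those of Cdkn1a (0.272), Mfsd2a (0.561) and Tsc22d3 (0.121) were lost with both risperidone groups fitted as 1 group. The glucocorticoid-responsive list had 11 of 20 members fallen over all genes and 14 adjusted over the list alone. Its median was −0.39 (adjusted p = 2.03e-05 with an estimated correlation). This joined 13 of 20 members fallen over all genes in pair-fed risperidone with 1 of 20 in ad libitum risperidone. The melanocortin and leptin feeding circuit had Mc4r fallen, 5 of 18 members fallen adjusted over the list alone and a median of −0.09 (adjusted p = 0.0276 with an estimated correlation). Its further examples Npy1r (−0.25), Cartpt (−0.29) and Mc3r (−0.34) did not pass. Markers of the paraventricular and supraoptic nuclei (−0.23), the arcuate nucleus (−0.10) and the lateral hypothalamus (−0.09) shifted lower in the same comparison, with adjusted p values of 0.00421, 0.0247 and 0.0165, and of 0.379, 0.656 and 0.238 with an estimated correlation. In all, 4 genes rose and 55 fell, with 1399 at an unadjusted p under 0.05. In this comparison 15 lists shifted, 4 higher and 11 lower, of which the glucocorticoid-responsive and feeding circuit lists held with an estimated correlation and with fry. The count of genes was 39, 36, 37 and 39 without control library 2, 4, 5 or 6, 99 without ad libitum library 1, 193 without ad libitum libraries 1 and 3, and 18 with both risperidone groups fitted as 1 group.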

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

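The tests of Mc4r against paraventricular markers within each feeding condition, the tests of the glucocorticoid-responsive genes against marker lists, and the fits without ad libitum libraries 1 and 3 were chosen only after the results were seen. The values of a library were compared with those of its own group by the gap to its nearest neighbour over the range of the group. Of 276 groups of values tested, 21 had a library that far from the others, where chance gives about 1 in 20. Ad libitum risperidone library 1 stood out in 6 of them and library 3 in 5. Control library 4 stood out in 3 and each other flagged library in 1, which chance alone could give.

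Ad libitum risperidone library 3 held 9748005 counts (17316043 to 18606543 in the rest of its group) and had a TMM factor of 0.731 (0.940 to 1.03). Of its counts 26.8% fell in genes annotated as or resembling ribosomal RNA (1.49% to 3.76%). It had mean log2 CPM values of 5.43 for the endoplasmic reticulum stress list (5.64 to 5.74) and 6.53 for the heat shock list (6.88 to 7.00). In ad libitum risperidone library 1 the mean log2 CPM was 6.06 for the markers of cortex, hippocampus and amygdala (3.07 to 3.88), 4.45 for those of striatum (4.00 to 4.19), 4.07 for those of the arcuate nucleus (4.38 to 4.62) and 4.87 for the immediate early genes (3.39 to 3.84). In the same library Penk stood at 206 CPM (146 to 169) and Fosb at 19 CPM (8.21 to 12).

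Among the controls, library 4 stood apart in Fos with 28.8 CPM (17.5 to 21.7), in Hr with 72.5 CPM (86.2 to 96.5) and in Fam107a with 361 CPM (391 to 408). Control library 7 had a mean log2 CPM of 2.70 for pericyte and fibroblast markers (3.39 to 3.89). Tanc1 stood at 24.6 CPM in control library 1 (19.8 to 21.8), Pfn4 at 6.87 CPM in control library 2 (7.92 to 8.40) and Twistnb at 20.2 CPM in control library 5 (17.8 to 18.5). In the pair-fed group the fatty acid synthesis list had a mean log2 CPM of 6.92 in library 3 (6.84 to 6.86), Arl4d stood at 6.01 CPM in library 5 (9.34 to 11.3) and Fam107a at 339 CPM in library 2 (262 to 291).

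Pair-fed and ad libitum risperidone differed in 71 genes, by the test between these groups, and the glucocorticoid-responsive genes had a median log2 difference of −0.36 between them. Among 100 splits of the libraries, the real one included, 1 gave as many genes as the real comparison did, in each comparison. The real counts were 11 in ad libitum risperidone against control (highest other 3) and 87 in pair-fed risperidone against control (highest other 1). They were 71 in pair-fed against ad libitum risperidone (highest other 56) and 59 in the mean of both risperidone groups (highest other 1). This argues against chance for these counts, but 100 splits cannot show a share below 1 in 100. For the counts of shifted lists chance cannot be excluded, since 18, 10, 14 and 14 of 100 splits gave as many as the real 14, 14, 16 and 15 (highest others 16, 17, 18 and 19).

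The glucocorticoid-responsive genes were lower in pair-fed risperidone than in control, with a median of −0.57. With the first component of the marker lists as a covariate the median was 0.998 of that value, but ad libitum library 1 held 0.772 of that component's sum of squares (3.83, others −0.818 to 0.551), so that this decides nothing. The 95% intervals of the clock genes Dbp, Nr1d1, Per2 and Arntl reached 0.459 at most, under the log2 of a 1.5-fold change, which argues against a shift in the time of collection large enough to move these genes 1.5-fold; a smaller shift stays open, since Dbp rose by 0.32 and Arntl stood at −0.15 (−0.299 to −0.00792). The medians of 20 of 21 marker lists lay above 0.5 of −0.57 by more than their errors over markers, the lowest being −0.126 (SE 0.0395, paraventricular and supraoptic nuclei). Astrocytes had −0.0387 (SE 0.0225) and endothelium 0.08. Their mean log2 CPM per library was 8.29 ± 0.028 and 4.65 ± 0.0845 (SD) in pair-fed risperidone, and 8.32 ± 0.0291 and 4.58 ± 0.0791 in control. This argues against a loss of astrocytes or endothelial cells as the cause. Lists with a wider spread between libraries leave a loss open, such as the paraventricular markers (4.93 ± 0.506 against 5.15 ± 0.213). A loss of pituitary tissue stays open too, because its 4 markers (−0.218, SE 0.12) were too few. A candidate explanation is a lower glucocorticoid signal in the pair-fed mice at the time of sampling, which the design joins to the drug, the amount of food and its timing, and no hormone level was measured here.

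Mc4r was lower in both risperidone groups, with a mean change of −0.49. Without ad libitum libraries 1 and 3 the change was 0.955 of that value (adjusted p = 0.0037, range over 33 settings 0.000635 to 0.0497), which argues against these libraries as the cause, while its ratio of 1.02 with the marker component as a covariate decides nothing, because the component mainly marks library 1. Less paraventricular tissue in the slices could account for a part. The 8 markers of the paraventricular and supraoptic nuclei had a median of −0.23 (SE 0.07) over both groups and of −0.33 (SE 0.10) in the ad libitum group. Of these markers 5 stand in other lists too. Lower expression in the same cells would also lower the median, so it need not measure the amount of tissue. Over both groups the median lay above 0.5 of the Mc4r change by less than its error. In the ad libitum group it lay between 0.5 and 0.75 of that change, so that the explanations cannot be told apart in either case. In the pair-fed group the median of these markers was −0.13 (SE 0.04), above 0.5 of the Mc4r change by more than its error over markers. That error leaves out the spread between libraries. Per library the list had a mean log2 CPM of 4.93 ± 0.506 (SD, n = 6) in pair-fed risperidone and 5.15 ± 0.213 (SD, n = 7) in control. Less paraventricular tissue therefore stays open there too. A direct effect of the diet on Mc4r and other differences in tissue makeup stay open.

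The immediate early genes were higher in pair-fed than in ad libitum risperidone, with a median of 0.17 by camera at its preset correlation, a call lost with an estimated correlation (adjusted p = 0.584) and with fry (0.263). Without ad libitum libraries 1 and 3 the median was 2.28 times as large (0.40), which argues against these libraries as the cause, and with the marker component as a covariate 2.95 times (0.51), which decides nothing on tissue makeup because the component mainly marks library 1. The clock gene intervals reached 0.508 at most, under the log2 of a 1.5-fold change, which argues against a shift in the time of collection that moves these genes 1.5-fold. A smaller shift stays open, since Dbp rose by 0.37 (adjusted p = 0.0103), Arntl stood at −0.17 (−0.319 to −0.0255) and Nr1d1 at 0.16 (−0.00553 to 0.335). Handling before sampling and the time since the last meal may differ between the feeding conditions, and neither was tested.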

How the results depend on the processing

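The fits without ad libitum libraries 1 and 3 and those with protein-coding genes alone were chosen only after the data were seen. The counts below are in the order ad libitum risperidone against control, pair-fed risperidone against control, pair-fed against ad libitum risperidone, the mean of both risperidone groups against control, and genes called in both with the same sign. They were 11, 87, 71, 59 and 6 with edgeR and TMM on 20 libraries. They stayed within 1.5 times of these values with RLE or upper-quartile scaling, no filter, a CPM filter, robust estimation and protein-coding genes alone. DESeq2 gave 113, 132, 167, 97 and 19 genes and limma-voom with quality weights 51, 223, 139, 151 and 21. Fits with 2 surrogate variables gave 55, 242, 143, 189 and 25, and fits with the marker component as a covariate 7, 140, 84, 93 and 2. Fits to the compared groups alone gave 3, 245, 31 and 1 genes in the first 3 comparisons and in the overlap, and a fit with both risperidone groups as 1 group gave 18 for their mean against control. Without ad libitum libraries 1 and 3 the counts were 48, 250, 142, 193 and 21. An adjusted p under 0.1 gave 49, 103, 155, 84 and 15. With 1 library left out they ranged from 0 to 35, 66 to 166, 39 to 130, 36 to 99 and 0 to 14. The cause was not tested except where an alternative used fewer libraries or a wider threshold.

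Gene lists shifted numbered 14, 14, 16 and 15 in the first 4 comparisons with camera at its preset correlation, 0, 1, 1 and 2 with an estimated correlation (6 lists at an unadjusted p under 0.05 where the count was 0), and 4, 2, 1 and 2 with fry. With 1 library left out they ranged from 10 to 16, 11 to 16, 12 to 16 and 12 to 17.

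The libraries carry numbers within their groups, and nothing in the labels pairs them. Deviations from the group means had a mean correlation of −0.00723 over the 19 pairs with the same number (−0.158 to 0.304), with 2 above 0.1, and 0 of 20 libraries matched best with their own number. With the number as a block the counts were 1, 65, 48, 45 and 0 genes with edgeR.

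Named genes whose values changed sign were not past the test in any setting, and the cause was not tested. Ranges are those with 1 library left out. Mc4r, risperidone pair-fed against risperidone ad libitum (0.01), was −0.00203 with DESeq2, −0.0287 with limma-voom, −0.0466 with 2 surrogate variables and −0.0417 without ad libitum libraries 1 and 3 (−0.0479 to 0.0521). Drd2, risperidone ad libitum against control (−0.05), was 0.050001 with limma-voom, 0.0980 with surrogate variables, 0.0653 with the marker component and 0.0854 without ad libitum libraries 1 and 3 (−0.112 to 0.0617). Drd2, mean of both risperidone groups against control (−0.05), was 0.00447, 0.00579 and 0.00994 with the last 3 of these, while its range held to 1 sign. Drd2, risperidone pair-fed against risperidone ad libitum (−0.02), was 0.0121 with the block (−0.125 to 0.0485). Htr2a, risperidone ad libitum against control (0.07), was −0.0251 with surrogate variables, −0.0715 with the marker component and −0.00482 without ad libitum libraries 1 and 3 (−0.0201 to 0.137). Htr2a, mean of both risperidone groups against control (−0.01), ranged from −0.0516 to 0.0268. Htr2c, risperidone pair-fed against risperidone ad libitum (0.04), was −0.0400 with limma-voom (−0.0576 to 0.0951). Npy, risperidone pair-fed against risperidone ad libitum (0.02), ranged from −0.0582 to 0.121. Agrp, mean of both risperidone groups against control (0.05), ranged from −0.00965 to 0.105.

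The 10 genes named among those that fell in pair-fed risperidone, Cdkn1a to Mertk, passed the test in all 33 settings, as did Sox21 and Penk there, while other genes that rose or fell there lost the call in up to 22 settings (Pfn4). The upper-quartile scaling moved the share of lower genes in ad libitum risperidone from 72.7% (8 of 11 genes) to 81.8% (9 of 11), which is too few genes to show an effect on direction. At 19 to 141 counts per library, depth limits what can be said of Mc4r in single libraries.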

Other observations

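The fits without ad libitum libraries 1 and 3 were chosen only after the results were seen, as were the correlations within groups and without these libraries. In pair-fed risperidone against control, genes of the respiratory chain and of cholesterol synthesis shifted higher by small amounts with camera. The nuclear-encoded respiratory chain had a median of 0.08 with 69 of 70 members higher (adjusted p = 0.618 with an estimated correlation), with Cox7a2 at 0.18 and Uqcrh at 0.22. Mitochondrially encoded transcripts had a median of 0.11 with 14 of 15 higher (0.618), with mt-Nd3 at 0.28, and cholesterol synthesis a median of 0.08 with 24 of 25 higher (0.425), with Mvd at 0.23 and Insig1 at 0.19. The members of these lists did not pass the test over all genes or adjusted over the list alone. Oligodendrocyte markers had a median of 0.18 with 14 of 14 higher (0.618) and 1 risen adjusted over the list alone, and Opalin, a myelin protein gene, stood at 0.65 (SE 0.172, adjusted p = 0.138). Markers of microglia (0.07), endothelium (0.08) and the mammillary nuclei (0.24) and the cytoplasmic ribosomal proteins (0.05) shifted higher too, and heat shock genes (−0.08) and other neuropeptides (−0.12) lower, with adjusted p values of 0.618, 0.618, 0.634, 0.775, 0.618 and 0.514 with an estimated correlation.

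Between the risperidone groups the ribosomal protein list had a median of 0.12 with 74 of 77 members higher (adjusted p = 0.584 with an estimated correlation), and of 0.05 without ad libitum libraries 1 and 3. Atf3, a transcription factor of the stress response, rose by 0.83 (adjusted p = 0.0434) and Dnajb1, a heat shock chaperone gene, by 0.31 (adjusted p = 0.0414), while Vgf, a neuropeptide precursor gene, fell by 0.28 (adjusted p = 0.0403). These calls were lost in 20, 17 and 13 of 33 other settings, with adjusted p values up to 0.132, 0.197 and 0.138. The oligodendrocyte markers shifted higher there with camera (adjusted p = 0.0194, and 0.647 with an estimated correlation). Their median was 0.06, and −0.15 without ad libitum libraries 1 and 3, so that their direction turned. The lists of aminergic receptors, with medians of 0.06 in ad libitum and −0.08 in pair-fed risperidone against control, dopamine synthesis (−0.07 and 0.01), prolactin and JAK-STAT feedback (−0.02 and 0.01), fatty acid synthesis (−0.02 and −0.01), the circadian clock (0.03 and 0.02) and inflammation (−0.09 and −0.02) did not shift in any of the 4 comparisons with camera.

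It was asked whether Mc4r falls together with the glucocorticoid-responsive genes in the same samples, as a hypothesis that both follow 1 signal. After the group means were removed, Mc4r and the mean of the list had a correlation of −0.435 over 20 libraries (permutation p = 0.137, Spearman −0.182). This is not the positive value that the hypothesis asks for. Ad libitum libraries 1 and 3 were the 2 farthest on the list mean, and without them the correlation was −0.0376. Within groups the correlation was 0.44 in control (n = 7, exact p = 0.331) and −0.494 in pair-fed risperidone (n = 6, exact p = 0.306). In ad libitum risperidone it was −0.799 (n = 7, adjusted p = 0.0365, Spearman −0.857 with an adjusted p of 0.0952). That value includes libraries 1 and 3, was not computed without them and rests on 19 to 93 Mc4r reads per library. The value over all libraries lay below 0 without passing the permutation test, and the question stays open.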
